A study of Homo sapiens with 12 samples.

How the data were processed

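RNA was sequenced from CCRF-CEM cells, a human T lymphoblast leukemia line, as the SLFN11-positive parent and as cells labelled SLFN11 knockout. Cells of each of the 2 genotypes received 100 nM camptothecin for 4 h or the solvent DMSO, which made 4 groups of 3 libraries. Camptothecin traps DNA topoisomerase I on DNA, and SLFN11 is a putative helicase that sensitizes cancer cells to such drugs. Per the labels' protocols, cells grew in RPMI1640 with 10% serum, RNA was purified with a DNase step, RNA integrity numbers were above 8.0, and the pooled libraries went through a single HiSeq4000 paired-end run. The library name in the label of parent control replicate 1 has another pattern than the other 11, and whether it was prepared or sequenced apart was not checked. The labels do not say how the knockout was made, whether it is a single clone, or whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

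The deposited tables gave, per gene and library, whole-number counts of reads over the gene, its exons and its introns, and the same counts for the stretches that no other gene overlaps, per the file headers. Trim Galore 0.6.2, Trimmomatic 0.39, STAR 2.5.4a, Picard 2.9.2 and the hg19 genome build are named per the submitters' processing notes, without their roles. The names of the deposited tables mark sorted alignments with duplicates removed. Duplicate removal without molecular identifiers compresses the counts of abundant and short transcripts. The counting tool, the annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are marked uncertain. Counts with more than 6 digits were written with 6 significant digits. The tables also hold TPM values that the authors scaled to the length and total of each table, and those TPM values were not used for any test.

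The 12 tables together listed 43828 gene places, and a gene missing from a table was given 0 reads. Copies of pseudoautosomal genes on the Y chromosome were left out, up to 32 per table, and 182 gene names that stood at more than 1 place were kept apart by position. Exon reads per library ran from 42439957 to 135592046. Exon counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 23546 genes, TMM set the scale, and 1 quasi-likelihood model with a robust prior and a mean per group was fitted to all 12 libraries. The common dispersion was 0.0137, a biological coefficient of variation of 11.7%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. There were 4 comparisons: the camptothecin response of parent cells, that of knockout cells, the difference of both responses (knockout minus parent), and untreated knockout against untreated parent cells. Levels are exon counts scaled to the TMM-adjusted library size (CPM) as mean ± SD. Log2 changes carry a standard error (SE) derived from the test. It is the absolute log2 change before edgeR's shrinkage, divided by the square root of the quasi-likelihood F statistic. These errors therefore restate the test and are no separate estimate of precision. Every adjusted p of a single gene comes from edgeR's quasi-likelihood test. Floors of 3 counts and counting intervals at 95% (exact binomial) cover counting error only, because the reads had no molecular identifiers.

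The comparisons, tests, alternatives, 19 gene lists and the rule for naming genes were fixed before the data were examined, except 1 added alternative and the tests of patterns and hypotheses that arose from the results. The lists held immediate early, p53 target, NF-kappaB target, interferon-stimulated, ATF4 and unfolded protein response, heat shock, replication-dependent histone, DNA replication, mitotic, DNA repair and checkpoint, BCL2 family, schlafen family, T lymphoblast, ribosomal protein and mitochondrially encoded genes. They also held B-lineage, myeloid, erythroid, and epithelial and fibroblast markers. The title of the series names activation of immediate early genes, so that list was chosen with the study's topic known. The rule named, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap in log CPM between the groups compared, or for the difference of responses in at least 1 of the treatment comparisons (chance alone gives 10% without overlap for 3 against 3), up to 4 members per list, and always SLFN11, FOS, JUN, EGR1, ATF3 and IER2. XIST and genes of the Y chromosome were left out of the named genes, and some genes that the rule names are not reported here. A count of 2 was added, in proportion to library size, before the log of CPM. Members named because a count was 5 or fewer were chosen after their values were seen.

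Lists were tested against all other genes with camera from limma 3.58.1, with its preset correlation of 0.01, adjusted over the 19 lists of a comparison. The alternatives were an estimated correlation between members and the self-contained test fry. Genes of at least 100 kb were compared with genes under 10 kb by genomic length. Camera tested each of the 2 classes against all other genes. An exact permutation test compared groups by each library's median log CPM of long genes minus that of short genes. Intron counts went through a second edgeR model of 19908 genes. The gene models were tested on simulated data with 200 genes, each with a mean of at least 1 CPM, changed by known amounts. Of the genes changed by 2-fold, 94% were recovered for the parent response, 91% for the knockout response, 70.1% for the difference of responses and 92.5% for the untreated cells, with 22937, 22916, 22931 and 22897 genes in the fits. At 1.5-fold these shares were 76.1%, 76.1%, 38.8% and 62.7%, and at 4-fold 98.5%, 98.5%, 100% and 100%. Of the calls in the simulated counts, 4.8% to 5.8% were unchanged genes.

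The alternatives were other scalings (median-of-ratios size factors, library size alone), other filters on low counts, DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, total gene reads, reads unique to a gene, other length limits and definitions, and leaving out each library in turn. After the data were seen, a fit without parent control replicate 1 and knockout camptothecin replicate 3 was added. GC content was taken from GENCODE transcripts matched by gene name, from another build whose coordinates were not used. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.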

Results

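Exon and intron reads of all annotated genes were counted in 12 libraries of CCRF-CEM leukemia cells, 3 each from untreated parent, camptothecin-treated parent, untreated knockout and camptothecin-treated knockout cells. Depth was 42439957 to 63606344 exon reads in 11 libraries and 135592046 in parent control replicate 1. That library stood apart from its group: a chi-square per degree of freedom of 190.9 and 149.9 separated its counts from the other parent controls, against 4.9 to 17.9 for every other pair within a group. This chi-square was scaled by library size without TMM factors and grows with depth, so its size mixes depth and composition with other differences. By this measure no pair differed by as little as sampling noise, and each library counted as 1 sample. The measure cannot tell separate cultures from technical repeats. Introns took 26.31% of reads in parent control replicate 1, the lowest share, and 33.55% in knockout camptothecin replicate 3, the highest. Mitochondrially encoded genes took 0.67% in parent control replicate 1 and 0.8% in knockout control replicate 3, against 0.41% to 0.48% elsewhere.

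SLFN11, the targeted gene (hg19 chromosome 17, 33677323 to 33700719), was still transcribed in the knockout cells. Its level was 112.3 ± 4.93 CPM in untreated parent cells and 86.92 ± 1.58 CPM in untreated knockout cells (SD, n = 3 libraries per group), a log2 difference of -0.37 ± 0.06 (SE, edgeR adjusted p = 0.000133). Camptothecin left 120.2 ± 2.38 CPM in parent and 89.84 ± 1.72 CPM in knockout cells. Its log2 changes were 0.10 in parent cells (edgeR adjusted p = 0.191) and 0.05 in knockout cells (adjusted p = 0.635), and the difference of responses was -0.05 (adjusted p = 0.791). SLFN11 intron reads went the other way: they were higher in untreated knockout cells by 0.58 ± 0.07 (edgeR adjusted p = 9.43e-07). Per library, 3.37 to 4.3 exon reads were counted per intron read in the parent and 1.63 to 1.97 in the knockout. Whole-gene counts cannot show a small insertion or deletion, so the level of this RNA checks the labels only in part. With total gene reads, counted over the whole gene, the untreated difference was -0.12 (edgeR adjusted p = 0.137). The parent response of SLFN11 was 0.13 without parent control replicate 1 (adjusted p = 0.0129), and with library size alone its responses were 0.22 in parent and 0.20 in knockout cells (adjusted p = 0.00148 and 0.00575).

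The first question was what camptothecin did in parent cells within 4 h. JUN, a subunit of the AP-1 transcription factor (chromosome 1, 59246464 to 59249784), rose 14.6-fold, from 44.88 ± 3.25 to 654.7 ± 20.8 CPM (SD, n = 3; log2 change 3.87 ± 0.07 SE; edgeR adjusted p = 6.8e-16). FOS, its AP-1 partner (chromosome 14, 75745476 to 75748932), rose from 1.493 ± 0.117 to 17.43 ± 2.01 CPM, and the zinc finger factor EGR1 (chromosome 5, 137801178 to 137805003) from 1.582 ± 0.238 to 22.1 ± 0.849 CPM. ATF3 (chromosome 1, 212738675 to 212794118) rose from 11.09 ± 0.342 to 113.4 ± 3.42 CPM and IER2 (chromosome 19, 13261228 to 13265721) from 43.09 ± 7.66 to 177.7 ± 5.15 CPM. The largest rise was in DUSP8, a phosphatase of MAP kinases, at 70.6-fold (0.6358 ± 0.352 to 40.21 ± 1.33 CPM). ARC rose 25.2-fold, RHOB 21.4-fold, the MAP kinase phosphatase DUSP4 19.1-fold, RGS16 16.9-fold, the chemokine IL8 13.5-fold and the cell cycle inhibitor CDKN1A 11.8-fold. RELB, a subunit of NF-kappaB, rose by 4.17 ± 0.15 on the log2 scale.

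The steepest fall in parent cells was that of the DNA helicase PIF1, from 21.06 ± 2.74 to 1.852 ± 0.124 CPM (11.3-fold; n = 3 per group). The mitotic kinase PLK1 fell 6.65-fold, from 84.99 ± 9.01 to 12.79 ± 0.25 CPM. ADM fell 5.32-fold, HSPA6 5.29-fold and ST6GALNAC3 5.12-fold. PLCB1 fell 4.94-fold and PTPRD 4.68-fold, and RP11-103C16.2 fell by 2.30 on the log2 scale. HSPA1L fell 5.36-fold and HSPA1A 4.88-fold, and both counts are uncertain because these genes share near-identical copies. Across the 23546 genes tested, 3961 rose and 4017 fell, of which 571 and 573 changed by at least 2-fold. With library size alone as the scale, the median of all genes was 0.14 in place of 0.01, and 67.2% of the called genes were higher in place of 49.6%.

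Among the lists, 35 of 38 measured immediate early genes rose and 1 fell in parent cells, the same counts when adjusted over the list alone. Their median log2 change was 2.11 (camera adjusted p = 9.6e-28; adjusted p = 9.29e-05 with an estimated correlation). KLF2, a factor of quiescent lymphocytes, was the member that fell (by 0.59, edgeR adjusted p = 0.00753), and FOSL1 (-0.33) and TRIB1 (0.73) did not pass the test. BTG2 rose by 2.47 ± 0.07 and JUNB by 2.26 ± 0.07. Of 15 NF-kappaB target genes, 14 rose and 0 fell, also when adjusted over the list alone (median 1.25, camera adjusted p = 3.27e-12; adjusted p = 0.0173 with an estimated correlation). NFKB2 rose 8.02-fold, TNF 3.08-fold and the inhibitor NFKBIA 3.27-fold, while NFKB1 stood at -0.04 (edgeR adjusted p = 0.743).

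Of 20 p53 target genes, 8 rose and 2 fell, or 13 and 3 adjusted over the list alone (median 0.32, camera adjusted p = 0.0033; adjusted p = 0.0676 with an estimated correlation). Their largest rises were CDKN1A at 3.56 ± 0.19 and the apoptosis gene BBC3 at 3.44 ± 0.25, while BAX (-0.23) and ZMAT3 (-0.46) fell. In the BCL2 family, 6 of 15 members rose and 3 fell, the same adjusted over the list alone, with MCL1 at 0.70 and PMAIP1 at 0.96. The list had a camera adjusted p of 0.162, and of 0.0285 with total gene reads. BCL2L1, BCL2A1 and BAX were the members that fell. Of 16 ATF4 and unfolded protein response genes, 7 rose and 5 fell (7 and 7 adjusted over the list alone; median -0.04, mean 0.24, camera adjusted p = 0.617). DDIT3 rose by 1.35 ± 0.07, and HSPA5 and DDIT4 fell. Interferon-stimulated genes went both ways, with 5 of 21 up and 4 down, also adjusted over the list alone (camera adjusted p = 0.617). IRF7 rose by 1.99 ± 0.10.

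Mitotic and heat shock genes fell in parent cells. All mitotic genes except MKI67 fell, 25 of 26 (26 adjusted over the list alone), with a median of -1.09, CCNB1 at -1.57 ± 0.07 and CDC20 at -1.34 ± 0.06 (camera adjusted p = 5.7e-21; adjusted p = 0.0825 with an estimated correlation). All 11 heat shock genes fell, also adjusted over the list alone, with a median of -0.70 and DNAJB1 at -1.31 ± 0.08 (camera adjusted p = 4.84e-09; adjusted p = 0.145 with an estimated correlation). Of 39 DNA replication genes, 24 rose and 4 fell (24 and 5 adjusted over the list alone; median 0.26, camera adjusted p = 5.24e-05; adjusted p = 0.375 with an estimated correlation). GINS3 rose by 0.87 ± 0.07, CDC6 by 0.85 ± 0.07 and CDT1 by 0.66 ± 0.06, and RPA1, POLA1, PRIM1 and RRM1 fell. Of 29 DNA repair and checkpoint genes, 7 rose and 11 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.161), with the kinase ATM at -0.68 ± 0.06.

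Genes of T lymphoblast identity fell in 20 of 27 cases and rose in 0, also adjusted over the list alone (median -0.43, camera adjusted p = 8.95e-09; adjusted p = 0.0162 with an estimated correlation). LEF1 fell by 1.24 and CD1A by 1.09 on the log2 scale. Of 25 ribosomal protein genes, 13 fell and 0 rose (14 adjusted over the list alone; median -0.23, camera adjusted p = 0.00237; adjusted p = 0.433 with an estimated correlation). Replication-dependent histone genes rose in 13 of 35 cases and fell in 2, HIST1H1E and HIST1H4D (14 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.00696; adjusted p = 0.521 with an estimated correlation). Mitochondrially encoded genes had a median of -0.28 (camera adjusted p = 0.162), -0.40 without parent control replicate 2 (adjusted p = 0.0281) and 0.012 without parent control replicate 1 (adjusted p = 0.638). MT-CO1 was the member called lower, at -0.42, and 0 members passed adjusted over the list alone. Without parent control replicate 1 MT-CO1 stood at -0.20, and its call ended without parent camptothecin replicate 1 or 2 (adjusted p 0.0503 to 0.0616), with library size alone (0.0612) and with only the groups compared (0.0641). In the schlafen family, SLFN5 fell by 0.49, and SLFN11, SLFN12 and SLFN13 did not pass the test (list median 0.03, mean -0.04, camera adjusted p = 0.989).

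Markers of other blood and tissue cells gave no list call in parent cells. The medians were -0.40 for 5 B-lineage markers (camera adjusted p = 0.125), 1.05 for 3 myeloid markers (adjusted p = 0.208), 1.92 for 4 erythroid markers (adjusted p = 0.166) and 0.15 for 4 epithelial and fibroblast markers (adjusted p = 0.761). VPREB1 and CD79A fell, and CEBPA and CSF1R rose. The myeloid and erythroid members had median levels of only 0.367 and 0.204 CPM over the 12 libraries. Their log2 changes therefore rest on low counts. The globin gene HBA1 rose by 3.19 ± 0.98 (edgeR adjusted p = 0.0171), with reads that may belong to HBA2, and without parent camptothecin replicate 1 its adjusted p was 0.0606. With total gene reads, CSF1R stood at -0.01 (adjusted p = 0.962).

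**Figure D1:**
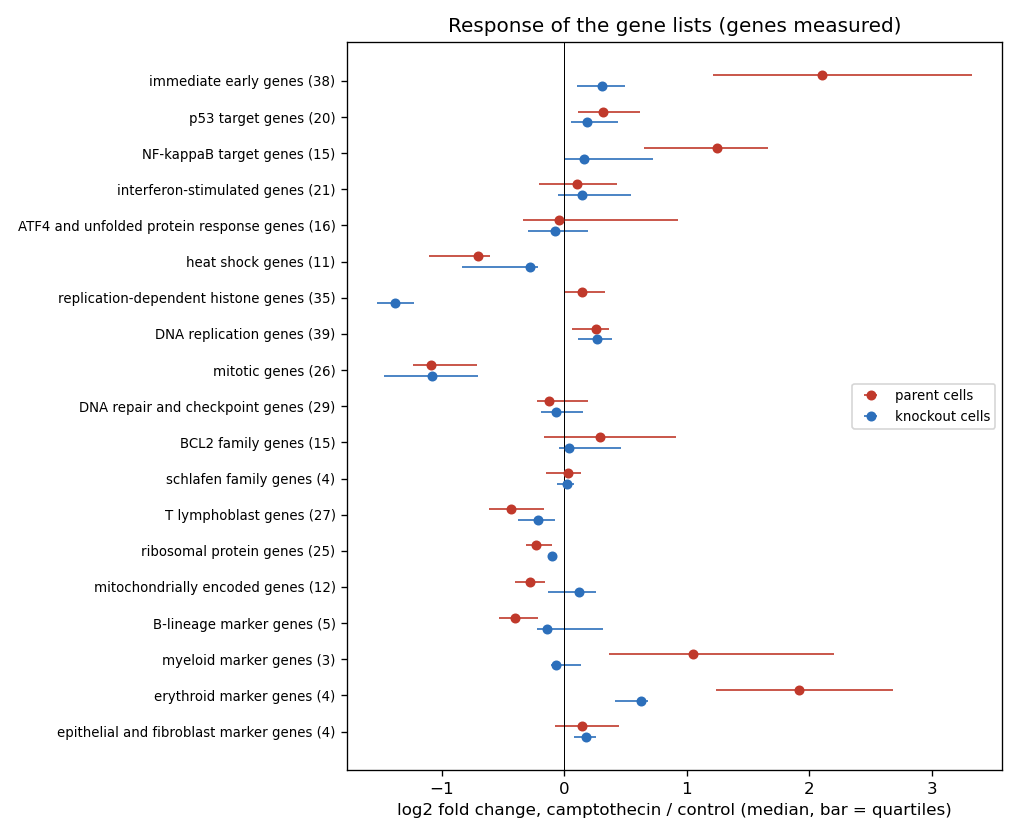
Median log2 change after camptothecin (x axis) of the measured members of each gene list (y axis, number measured in brackets), for parent cells in red and knockout cells in blue, with bars from the first to the third quartile. Immediate early genes had a median of 2.11 in parent and 0.31 in knockout cells, and histone genes 0.15 and -1.38, while mitotic genes had -1.09 and -1.08.

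The second question was how cells labelled knockout responded to the same treatment. Their strongest changes were falls: PIF1 fell 11.9-fold, from 20.12 ± 2.15 to 1.692 ± 0.113 CPM (SD, n = 3 per group; log2 change -3.57 ± 0.13 SE; edgeR adjusted p = 1.74e-11). HSPA6 fell 10.9-fold, PLK1 6.28-fold and PLCB1 3.91-fold. Core histone genes, whose messages belong to S phase, fell too: HIST1H2BM fell 5.64-fold (147.2 ± 3.44 to 26.08 ± 1.21 CPM), HIST1H2BF 4.06-fold and HIST1H2BB 3.68-fold, and the testis-type HIST1H1T fell 3.78-fold. RP11-80G7.1 fell by 2.01 and RP5-998N21.10 fell by 1.96 on the log2 scale, and the call for RP5-998N21.10 ended in 6 of the 12 fits that each left out 1 library (adjusted p 0.0537 to 0.114 there: without parent camptothecin replicate 2, knockout control replicates 2 and 3, or any treated knockout library). It also ended with only the groups compared (0.053). The rises were smaller: IL8 rose 4.46-fold (0.1222 ± 0.109 to 0.5464 ± 0.0556 CPM), IL6ST 3.21-fold, RELB 2.97-fold, IGSF3 2.91-fold, the tissue factor gene F3 2.63-fold, TTC3P1 2.54-fold, FGFR3 2.52-fold and MB21D2 2.5-fold. FLJ27365 rose 2.53-fold, with adjusted p of 0.0541 and 0.0598 without knockout control replicate 3 or knockout camptothecin replicate 2. With total gene reads, PLCB1 stood at -0.19 (adjusted p = 0.157) and IL6ST at 0.01 (adjusted p = 0.965).

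Most immediate early genes did not pass the test in knockout cells. FOS was 1.812 ± 0.308 CPM before and 1.622 ± 0.296 CPM after camptothecin (log2 change -0.17, edgeR adjusted p = 0.583), and IER2 stood at -0.18 (adjusted p = 0.247). JUN (0.19, adjusted p = 0.0414), ATF3 (0.20, adjusted p = 0.0383) and EGR1 (0.50, adjusted p = 0.0257) passed the test by a small margin. The JUN call ended in 9 of 12 fits that left out 1 library, all but those without a parent control. The ATF3 call ended in 8, the same fits except that without knockout camptothecin replicate 3, and the EGR1 call in 3, without knockout control replicate 1 or 3 or knockout camptothecin replicate 3 (highest adjusted p 0.162, 0.155 and 0.121). For JUN the call also ended with no filter and with total gene reads (adjusted p = 0.139 and 0.165). For ATF3 it ended with these and with only the groups compared (0.0512 to 0.349). For EGR1 it ended with only the groups compared (0.0585). IER2 passed the test without parent control replicate 1 (adjusted p = 0.0103) and with only the groups compared (0.0176). Over the list, 13 of 38 rose and KLF6 fell (21 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.54e-05; adjusted p = 0.0208 with an estimated correlation). JUNB rose by 0.47 ± 0.07 and NR4A1 by 0.64 ± 0.10.

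Replication-dependent histone genes fell in 34 of 35 cases, all but HIST1H1A (-0.11, edgeR adjusted p = 0.917), also adjusted over the list alone, and their median was -1.38 (camera adjusted p = 3.39e-45; adjusted p = 0.0208 with an estimated correlation). HIST1H2AC fell by 1.63 and HIST1H1D by 1.48 on the log2 scale. These genes share near-identical coding sequences, so single members are uncertain. Mitotic genes fell in 25 of 26 cases, all but MKI67, also adjusted over the list alone (median -1.08, camera adjusted p = 7.23e-33; adjusted p = 0.034 with an estimated correlation). Of 11 heat shock genes, 7 fell and 0 rose, also adjusted over the list alone (median -0.28, camera adjusted p = 1.98e-06; adjusted p = 0.21 with an estimated correlation). DNA replication genes rose in 21 of 39 cases and POLA1 fell (26 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 6.2e-10; adjusted p = 0.197 with an estimated correlation). The cyclin CCNE2 rose by 1.07 ± 0.09 and PCNA by 0.60 ± 0.06. T lymphoblast genes fell in 13 of 27 cases (15 adjusted over the list alone; median -0.22, camera adjusted p = 4.46e-07; adjusted p = 0.0208 with an estimated correlation).

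Of the other lists in knockout cells, NF-kappaB targets rose in 6 of 15 cases and NFKB1 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 0.00676; adjusted p = 0.241 with an estimated correlation), with CD83 at 1.20 ± 0.09. Of 20 p53 targets, CDKN1A, PHLDA3, ZMAT3, AEN and TP53INP1 rose and FAS and CCNG1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00676; adjusted p = 0.0742 with an estimated correlation). The ZMAT3 call ended without knockout control replicate 1 or 3 or knockout camptothecin replicate 3 (adjusted p 0.0711 to 0.104). It also ended with total gene reads (0.081). The CCNG1 call ended with library size alone (adjusted p = 0.0539) and with reads unique to a gene (0.155). Of 21 interferon-stimulated genes, IFIT2, MX1, OAS3, IRF7 and USP18 rose (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.0239; adjusted p = 0.197 with an estimated correlation), a list call that ended without knockout camptothecin replicate 1 (adjusted p = 0.0647). Ribosomal protein genes had 0 members called and a median of -0.10 (camera adjusted p = 0.0342; adjusted p = 0.64 with an estimated correlation), which became 0.06 with library size alone. Without knockout control replicate 3 or knockout camptothecin replicate 3 that list had adjusted p of 0.06 and 0.488. No list call was made for ATF4 and unfolded protein response genes (3 up, 5 down; camera adjusted p = 0.403), DNA repair genes (4 up, 7 down; 0.495), the BCL2 family (3 up, 1 down; 0.218), schlafen genes (0.887) or mitochondrially encoded genes (0.67). The same held for B-lineage (median -0.14, mean 0.29; 0.861), myeloid (median -0.06, mean 0.04; 0.861), erythroid (0.861) and epithelial and fibroblast markers (0.705).

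In all, 1718 genes rose and 2184 fell in knockout cells, of which 153 and 275 changed by at least 2-fold. Without parent control replicate 1, which enters this comparison through the shared estimate of spread, the filter and the scale, 6640 genes were called in place of 3902, and without knockout control replicates 1, 2 or 3 there were 2519, 2571 and 2586. Those that rose numbered 1090 without knockout camptothecin replicate 1. With library size alone as the scale the median of all genes was 0.17 in place of 0.02, and 78.6% of called genes were higher in place of 44%. The genes higher in both genotypes numbered 1127 (289 for independent lists) and those lower in both 1754 (373), while 61 were higher in parent and lower in knockout cells (367 for independent lists) and 8 the reverse (293). Across genes, which are not independent replicates, Pearson's r of the responses was 0.41 and Spearman's rho 0.48.

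**Figure D2:**
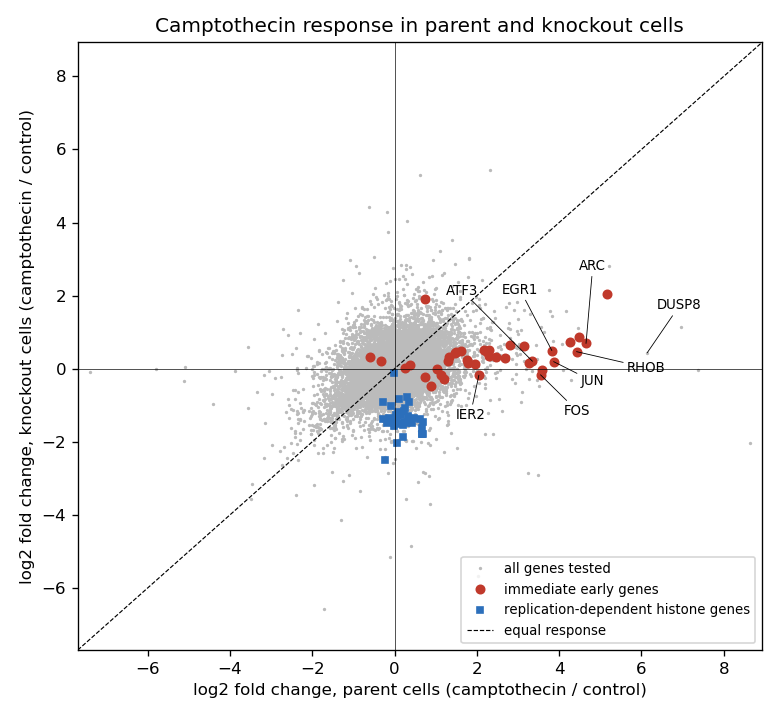
Log2 change after camptothecin in parent cells (x axis) and in knockout cells (y axis) for each gene tested in gray, with immediate early genes in red, replication-dependent histone genes as blue squares, and a dashed line of equal response. JUN lies at 3.87 in parent and 0.19 in knockout cells and DUSP8 at 6.14 and 0.44, while most histone genes lie below 0 in knockout cells alone.

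The central question was where both responses differed, tested as the difference itself (knockout minus parent). Immediate early genes responded less in knockout cells: the difference was -3.67 ± 0.09 for JUN (edgeR adjusted p = 1.29e-13), -3.71 ± 0.23 for FOS (1.22e-08), -3.33 ± 0.20 for EGR1 (6.57e-09), -3.15 ± 0.09 for ATF3 (8.63e-13) and -2.23 ± 0.14 for IER2 (2.02e-08). In each of these 5 genes, all 3 treated parent libraries lay above all 9 others. Apart from these 5 genes, the most negative differences among the named genes were those of DUSP8 (-5.71 ± 0.35), ARC (-3.96), RHOB (-3.96), DUSP4 (-3.52), RGS16 (-3.41) and NR4A3 (-3.13). RHOB and DUSP4 were already higher in untreated knockout than in untreated parent cells, at 4.898 ± 0.492 against 0.2397 ± 0.156 CPM and at 3.095 ± 0.282 against 0.4632 ± 0.166 CPM. After camptothecin RHOB stood at 6.763 ± 0.589 CPM in knockout and 5.174 ± 0.0853 CPM in parent cells. Over the list, 31 of 38 members had a more negative response in knockout cells and KLF2 a more positive one (33 and 1 adjusted over the list alone), with a median of -1.79 (camera adjusted p = 7.46e-44; adjusted p = 1.62e-05 with an estimated correlation).

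**Figure D3:**
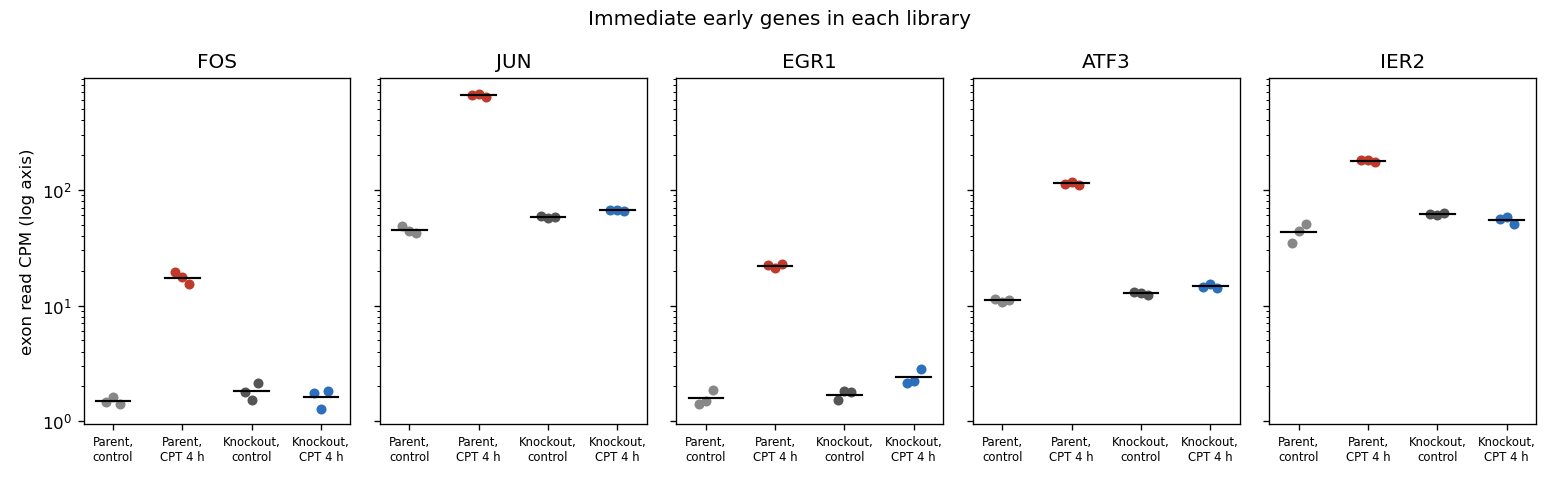
Exon read CPM on a log axis (y axis) of FOS, JUN, EGR1, ATF3 and IER2 in each of the 12 libraries, as points by group (x axis) with a line at the group mean. The 3 treated parent libraries stand above the rest in every panel, with JUN at a mean of 654.7 CPM against 44.88, 58.0 and 66.29 CPM in the other groups.

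NF-kappaB targets also had a more negative response in knockout cells, in 8 of 15 cases (12 adjusted over the list alone; median -1.20, camera adjusted p = 9.29e-16; adjusted p = 0.00774 with an estimated correlation), with RELB at -2.60 ± 0.21 and NFKB2 at -2.05 ± 0.10. Histone genes had a more negative response in knockout cells in 34 of 35 cases, all but HIST1H1A, also adjusted over the list alone (median -1.47, camera adjusted p = 1.18e-55; adjusted p = 0.00685 with an estimated correlation), with HIST1H2AC at -2.29 ± 0.08. Heat shock genes had a less negative response in knockout cells: HSPA1A (1.21), HSPA1B (0.82), HSPA8 (0.80) and HSPE1 (0.69) passed the test, and 9 did so adjusted over the list alone (median 0.34, camera adjusted p = 1.47e-06; adjusted p = 0.198 with an estimated correlation). Outside the list, the heat shock gene HSPA6 fell by more in knockout cells (log2 change -3.45) than in parent cells (-2.40). The HSPE1 call ended in 8 of 12 fits without 1 library (highest adjusted p 0.0936). Those were all but the fits without a parent control or knockout camptothecin replicate 3. Among T lymphoblast genes, CD2 (0.66), GATA3, CD247 and CD3G had a less negative response in knockout cells (8 genes adjusted over the list alone; median 0.16, camera adjusted p = 0.00105; adjusted p = 0.0963 with an estimated correlation), and the calls of GATA3 and CD247 each ended in 4 fits without 1 library and that of CD3G in 8 (highest adjusted p 0.0567, 0.0582 and 0.112). For GATA3 these lacked parent camptothecin replicate 1 or 3 or knockout control replicate 1 or 2. For CD247 they lacked parent camptothecin replicate 3, knockout control replicate 1 or 2 or knockout camptothecin replicate 1, and for CD3G the same libraries as for HSPE1. With total gene reads the HSPE1, CD247 and CD3G calls ended (adjusted p = 0.068, 0.11 and 0.116), and without a filter that of CD3G (0.0875).

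Of 16 ATF4 and unfolded protein response genes, DDIT3 (-1.74 ± 0.10) had a more negative response in knockout cells, CEBPB, SESN2, CHAC1 and TRIB3 responded less, and PSAT1, which fell in parent cells, had a more positive response (7 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.0334; adjusted p = 0.0963 with an estimated correlation). That list call ended without parent control replicate 3 (adjusted p = 0.0565). DDIT3 rose in parent cells and fell in knockout cells (-0.39, edgeR adjusted p = 0.00108), and its knockout call ended with reads unique to a gene (-0.094, adjusted p = 0.816). CDKN1A (-2.42 ± 0.25), BBC3 (-2.80 ± 0.35), PMAIP1 and AEN were the p53 targets that responded less, and ZMAT3, which fell in parent and rose in knockout cells, had a more positive response (4 and 1 adjusted over the list alone; camera adjusted p = 0.0806). CDKN1A started higher in knockout cells, at 6.299 to 7.92 CPM per untreated library against 1.284 to 2.477 CPM in parent cells. After camptothecin it stood at 13.33 to 17.55 CPM in knockout and 21.74 to 22.89 CPM in parent libraries. The p53 list had a median of -0.17 without parent control replicate 1 (adjusted p = 0.0219). In the BCL2 family MCL1, BBC3 and PMAIP1 responded less (median 0.13, mean -0.19, camera adjusted p = 0.705). Mitochondrially encoded genes had a median difference of 0.39 with 0 members called (camera adjusted p = 0.043; adjusted p = 0.661 with an estimated correlation), and without parent control replicate 1 it was 0.11 (adjusted p = 0.55). That call also ended without parent camptothecin replicate 1 or 2, any knockout control or knockout camptothecin replicate 3, and with total gene reads (0.11). B-lineage markers had 0.39 with 0 of 5 called (3 adjusted over the list alone; camera adjusted p = 0.043; adjusted p = 0.129 with an estimated correlation), a call that ended without parent control replicate 3, parent camptothecin replicate 3, knockout control replicate 1 or 2 or knockout camptothecin replicate 2 (adjusted p 0.0564 to 0.0945), and with library size alone (0.0544).

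No list call was made for the difference in mitotic genes (median -0.07, camera adjusted p = 0.187), of which CDC20 passed at -0.41, or in DNA replication genes (0.372), where CCNE2 and PCNA rose more in knockout cells and GINS3 less, and RPA1, which fell in parent cells, and RFC4 had a more positive response. The mitotic list had a median of -0.18 without parent control replicate 1 (adjusted p = 0.00011). The PCNA, RPA1 and BST2 calls ended in 9, 5 and 8 of 12 fits without 1 library (highest adjusted p 0.139, 0.089 and 0.102). Those fits lacked any parent camptothecin library or knockout control 2 or 3 for all 3 genes, knockout control 1 or knockout camptothecin 1 or 2 for PCNA and BST2, and parent control 2 for PCNA. With total gene reads the PCNA and BST2 calls ended (adjusted p = 0.152 and 0.0757), and without a filter that of PCNA (0.0922). No call was made either for DNA repair genes (0.247), of which PARP1 passed at 0.54, interferon-stimulated genes (0.187), of which IRF7 responded less and BST2, at -0.48 in parent and -0.08 in knockout cells, had a more positive response, ribosomal protein genes (0.109) or schlafen genes (median -0.01, mean 0.05; 0.888). The ribosomal list was called without knockout camptothecin replicate 3 (0.17, adjusted p = 0.0061) and with library size alone (adjusted p = 0.0219). Myeloid (0.177), erythroid (0.187) and epithelial and fibroblast markers (median 0.03, mean -0.07; 0.906) gave no call. The erythroid list was called without parent control replicate 2, parent camptothecin replicate 2, knockout control replicate 1 or knockout camptothecin replicate 3 (adjusted p 0.0234 to 0.0499).

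In all, 434 genes responded more positively and 1053 more negatively in knockout cells. Of the 1487, 711 rose in parent cells with no call in knockout cells, 159 rose in both but less in knockout cells, 209 fell in parent cells with no call in knockout cells, 155 fell in both but less in knockout cells, and 99 fell in knockout cells with no call in the parent. Of the 571 genes that rose at least 2-fold in parent cells, 201 differed, each with a smaller response in knockout cells, and choosing genes by their parent response favors such a direction. Of the 573 that fell at least 2-fold, 81 differed and 79 of these had the smaller response in knockout cells. Among the genes with a larger value in knockout cells, ARHGEF12 had 2 reads over the 3 untreated knockout libraries. Without parent control replicate 1, 3503 genes differed, and 903 to 972 without any 1 treated parent or untreated knockout library (parent camptothecin replicates 1, 2 and 3: 913, 903 and 972; knockout control replicates 1, 2 and 3: 952, 913 and 949). With library size alone, 46.3% of called genes were higher in place of 29.2%, and other settings that moved this share by over 10 points were no filter (40.4%) and leaving out both parent control replicate 1 and knockout camptothecin replicate 3 (41.6%). The genes with a more positive response numbered 260 and 225 without knockout camptothecin replicate 1 or 2.

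The untreated cells of both genotypes differed as well. KCNJ2, a potassium channel gene, was 65.4-fold higher in knockout cells, at 2.497 ± 0.26 against 0.02974 ± 0.0265 CPM (SD, n = 3 per group; log2 difference 6.03 ± 0.52 SE; edgeR adjusted p = 2.98e-07). LRRC6 was 33.7-fold higher, SHISA9 24.7-fold, the repressor gene KLF3 22.8-fold, RHOB 20.3-fold, TP53I11 13.6-fold, KREMEN1 13.3-fold, STON2 12.8-fold, DOCK5 12.5-fold and GFOD1 12.2-fold. PNMAL1 had 490 reads in the untreated parent libraries and 0 in the untreated knockout libraries, which makes it at least 113-fold lower against a floor of 3 counts over the group. ARHGEF12 had 1129 and 2 reads, a 391-fold lower level with a counting interval of 108 to 3240. CDC42BPA was 85.5-fold lower, ZNF626 49.0-fold, the transcription factor MEF2C 16.3-fold, the Wnt co-receptor LRP6 15.9-fold, the histone gene HIST1H1A 14.4-fold, LRRC2 14.2-fold, the granzyme GZMA 13.9-fold and CDHR1 13.6-fold. In all, 1945 genes were higher and 1752 lower in knockout cells, of which 656 and 315 by at least 2-fold. Without knockout control replicates 1, 2 or 3, 2440, 2385 and 2408 genes were called in place of 3697. With library size alone 72.7% of called genes were higher in place of 52.6%, and 62.5% when only the groups compared were fitted.

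Immediate early genes started higher in untreated knockout cells in 16 of 38 cases, with GADD45B lower (18 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 3.94e-05; adjusted p = 0.0419 with an estimated correlation). Of these, KLF6 was higher by 1.18 ± 0.10, NR4A3 by 1.78 ± 0.24, JUN by 0.37 ± 0.06 and IER2 by 0.53 ± 0.10, while FOS stood at 0.28 (edgeR adjusted p = 0.293) and EGR1 at 0.13 (adjusted p = 0.627). Of 20 p53 targets, 8 were higher and TNFRSF10B lower, also adjusted over the list alone (median 0.19, camera adjusted p = 0.015; adjusted p = 0.144 with an estimated correlation), with CDKN1A at 1.91 ± 0.19 and TP53I3 at 1.06 ± 0.13. Ribosomal protein genes were lower in 16 of 25 cases (17 adjusted over the list alone; median -0.26, camera adjusted p = 4.11e-06; adjusted p = 0.244 with an estimated correlation), with RPS2 at -0.52. ATF4 and unfolded protein response genes were lower in 8 of 16 cases (9 adjusted over the list alone; median -0.27, camera adjusted p = 0.00436; adjusted p = 0.0626 with an estimated correlation), with ATF4 at -0.61 and PSAT1 at -0.48. In the schlafen family SLFN12 (-0.91 ± 0.12), SLFN13 (-0.56 ± 0.11) and SLFN11 were lower and SLFN5 higher (0.52 ± 0.10), also adjusted over the list alone (median -0.47, camera adjusted p = 0.0352; adjusted p = 0.197 with an estimated correlation). That schlafen list call ended in all 10 fits that lacked a library other than knockout camptothecin replicate 1 or 3 (adjusted p 0.0578 to 0.12). It also ended with total gene reads (0.0983).

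Mitochondrially encoded genes had a median of -0.41 with 0 members called and 5 lower adjusted over the list alone (camera adjusted p = 0.00779; adjusted p = 0.493 with an estimated correlation), and -0.15 without parent control replicate 1 (adjusted p = 0.0524). Interferon-stimulated genes were lower in 7 of 21 cases, with OAS2 at -1.51 and MX1 and IRF7 higher (2 up and 8 down adjusted over the list alone; camera adjusted p = 0.0352; adjusted p = 0.244 with an estimated correlation), a list call that ended without parent control replicate 1 or knockout control replicate 3 (adjusted p = 0.0688 and 0.0535). DNA repair genes were lower in 6 of 29 cases (1 up and 9 down adjusted over the list alone), with PARP1 at -0.34 (camera adjusted p = 0.0352; adjusted p = 0.495 with an estimated correlation). Their list call ended without parent control replicate 1 or knockout control replicate 1 or 3 (adjusted p 0.0535 to 0.189) and with library size alone (0.18), and the PARP1 call with only the groups compared (0.0766). Histone genes had 5 of 35 lower, HIST1H1A, HIST1H2AB, HIST1H2AL, HIST1H2BF and HIST1H2BM, also adjusted over the list alone (median -0.11, camera adjusted p = 0.0352; adjusted p = 0.587 with an estimated correlation). That list call ended without parent control replicate 1 (adjusted p = 0.0524), with library size alone (0.102) and with total gene reads (0.0558). The HIST1H2AB call ended in 8 fits, without parent control 2 or 3, any parent camptothecin or any knockout control library, and the HIST1H2AL call in 7, without any parent camptothecin or knockout control library or knockout camptothecin 1 (highest adjusted p 0.136 and 0.123). Both ended too with library size alone (0.222 and 0.08), with only the groups compared (0.107 and 0.112) and with total gene reads (0.0508 and 0.0669). The HIST1H2AB call also ended without a filter (0.0586). Among epithelial and fibroblast markers the adhesion gene EPCAM was higher by 2.34 ± 0.17 (list camera adjusted p = 0.0352, and 0.244 with an estimated correlation). The list call ended without parent control 2 or 3 or knockout control 1 or 3 (adjusted p 0.0535 to 0.0602). It also ended with total gene reads (0.0633).

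T lymphoblast genes differed both ways in untreated cells, with 11 of 27 higher and 6 lower (12 and 7 adjusted over the list alone; camera adjusted p = 0.0898). CD1A was higher by 1.25 ± 0.08 and RAG1 by 0.62 ± 0.06, and CD7 was lower (-0.46 ± 0.06). That list was called without parent control replicate 1 (adjusted p = 0.0162). NF-kappaB targets also went both ways, with ICAM1, NFKB2, BIRC3 and TNF higher and NFKB1, IL8 and CD83 lower (5 up and 3 down adjusted over the list alone; median 0.01, mean -0.07, camera adjusted p = 0.505). DNA replication genes (2 higher, 5 lower; camera adjusted p = 0.0745), mitotic genes (0 called; 0.225) and heat shock genes (HSPA1A at 0.36; 0.808) gave no list call, nor did the BCL2 family (BCL2L2 and PMAIP1 higher; 0.0838). The HSPA1A call ended in 11 of 12 fits, all but that without parent control replicate 1, and the PMAIP1 call in 5, without parent control 2 or 3 or any knockout control (highest adjusted p 0.146 and 0.0971). Both ended with only the groups compared (0.157 and 0.111), and that of HSPA1A with median-of-ratios size factors (0.0573) and with total gene reads (0.0795). The BCL2 list was called without parent control replicate 2 (adjusted p = 0.0334), with library size alone (0.0416) and with total gene reads (0.0456). B-lineage (median 0.04, mean -0.81; 0.808), myeloid (0.25) and erythroid markers (0.193) gave none, the erythroid list only without knockout camptothecin replicate 1 (0.0365). Without parent control replicates 2 or 3, the DNA replication list (adjusted p = 0.0195 and 0.0214) and the mitotic list (lowest adjusted p = 0.0348) were called lower.

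Topoisomerase I, the target of camptothecin, relieves supercoiling ahead of RNA polymerase, and responses were therefore compared by gene length. Genes of at least 100 kb (2729) lay below genes under 10 kb (10666) in both genotypes. The medians differed by -0.33 in parent cells and by -0.23 in knockout cells. Tested against all other genes, long genes were called lower in parent cells (camera adjusted p = 4.66e-17; adjusted p = 0.0388 with an estimated correlation) and in knockout cells (1.51e-14; adjusted p = 0.0564 with an estimated correlation), and short genes were not called (0.156 and 0.103). With classes set by exon length the medians differed by -0.086 and -0.051, and with limits of 200 kb and 20 kb by -0.59 and -0.40. The 473 genes of 300 kb or more had medians of -0.76 and -0.52, and PTPRD and PLCB1 are long genes among the named falls. In parent cells 1242 long genes fell and 179 rose, and in knockout cells 898 fell and 95 rose. An exact two-sided permutation test of the long minus short difference in median log CPM per library gave p = 0.1 in both genotypes. That is the smallest p that 3 against 3 libraries allow. The length difference was less negative in knockout cells, by 0.12 (long genes against all others, camera adjusted p = 2.47e-05; adjusted p = 0.343 with an estimated correlation), a difference of 0.04 without parent control replicate 1 and of 0.03 by exon length (adjusted p = 0.186). In untreated cells the length classes differed by -0.04 (long genes against all others, camera adjusted p = 0.757).

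**Figure D4:**
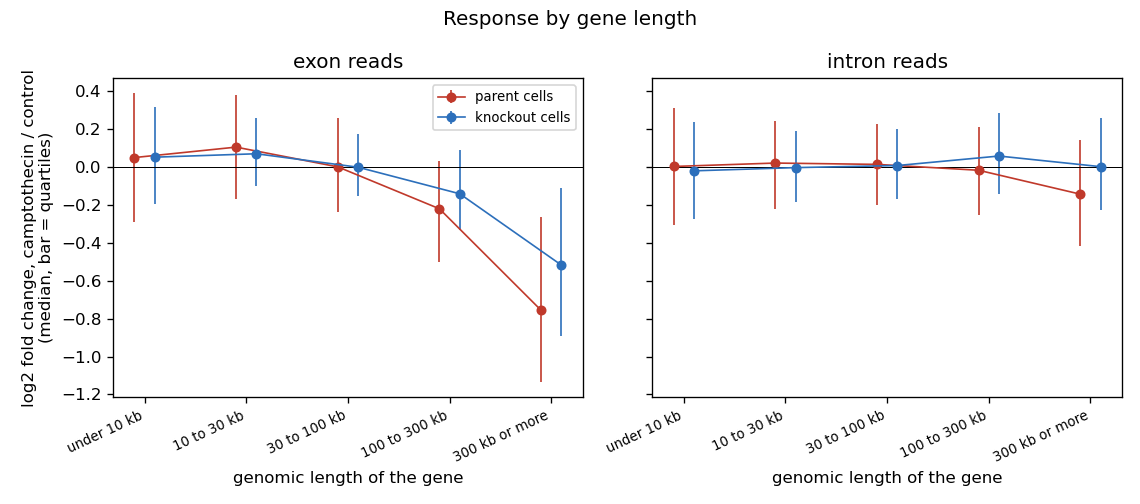
Median log2 change after camptothecin (y axis, bars from the first to the third quartile) by genomic length of the gene (x axis, kb), in parent cells in red and knockout cells in blue, for exon reads at left and intron reads at right. Exon reads of genes of 300 kb or more had medians of -0.76 and -0.52, and their intron reads -0.14 and 0.00.

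Intron reads, which come largely from unspliced RNA, were tested the same way. Immediate early genes with measured introns rose in 19 of 27 cases and fell in 0 in parent cells (median 1.46, camera adjusted p = 2.07e-13; adjusted p = 0.004 with an estimated correlation), and in knockout cells 1 rose and 2 fell (median 0.08, camera adjusted p = 0.834). The difference was called in 15 of 27, each more negative in knockout cells (median -1.22, adjusted p = 0.00229 with an estimated correlation). Mitotic genes fell in 25 of 26 cases in parent and in all 26 in knockout cells (medians -0.80 and -0.76). By intron reads 2400 genes rose and 2831 fell in parent cells, 1562 rose and 1801 fell in knockout cells, and 598 responded more positively and 560 more negatively in knockout cells. Of the genes called for that difference with both kinds of read, 349 of 349 had the same direction. By intron reads long genes were not called against all others within either genotype (camera adjusted p = 0.123 in parent and 0.0884 in knockout cells), with long minus short differences of -0.04 and 0.07. For the difference of responses they were called by intron reads too, where long minus short stood at 0.13 (camera adjusted p = 3.39e-05; adjusted p = 0.404 with an estimated correlation), with 331 long genes more positive and 58 more negative in knockout cells. Without parent control replicate 1, 1047 and 1010 genes differed in response, and without parent camptothecin replicate 1 it was 337 and 353, without parent camptothecin replicate 2 343 and 365. Without knockout control replicates 1, 2 or 3 the genes with a more positive response were 390, 383 and 330, and those that rose in knockout cells 957, 1039 and 955.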

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

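The tests of parent control replicate 1, of scaling and of the higher start of immediate early genes in knockout cells were chosen only after the result was seen. Each result here was singled out because the camptothecin response differed between parent and knockout cells by a test of the difference itself (knockout minus parent). By exon reads, 434 genes had a more positive and 1053 a more negative response in knockout cells, and by intron reads 598 and 560. The list medians were -1.79 for immediate early genes, -1.20 for NF-kappaB targets, -1.47 for replication-dependent histone genes, -0.13 for ATF4 and unfolded protein response genes, 0.34 for heat shock genes, 0.16 for T lymphoblast genes, 0.39 for mitochondrially encoded genes and 0.39 for B-lineage markers. The response of long minus short genes differed by 0.12. With an estimated correlation the first 3 of these 8 lists held, and the others had camera adjusted p of 0.0963, 0.198, 0.0963, 0.661 and 0.129 in the order given, and the length difference 0.343.

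Among single genes the most negative differences were DUSP8 (-5.71), ARC (-3.96), RHOB (-3.96), FOS (-3.71), JUN (-3.67), DUSP4 (-3.52), RGS16 (-3.41), EGR1 (-3.33), ATF3 (-3.15) and NR4A3 (-3.13). The most positive were ARHGEF12 (4.05), CDC42BPA (1.88), IGSF3 (1.69), HSPA1L (1.59), RP11-187C18.2 (1.40), FLJ27365 (1.39), FRMD4B (1.29), PPM1H (1.25), HSPA1A (1.21) and IGHV3-15 (1.21). ARHGEF12 and CDC42BPA stood at 0.01296 and 0.1069 CPM in untreated knockout cells. Calls ended for HSPA1L in 7, FLJ27365 in 11, FRMD4B in 7 and IGHV3-15 in 8 of 12 fits without 1 library. The CDC42BPA call ended without knockout control replicate 2 or knockout camptothecin replicate 3 (highest adjusted p 0.06). It also ended with total gene reads (0.71 in place of 1.88). The RP11-187C18.2 call ended without parent camptothecin replicate 1 (highest adjusted p 0.055).

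Immediate early genes rose in parent cells and responded less in knockout cells. The values argue against parent control replicate 1 as the source (median difference -1.88 without it). With library size alone the median difference was -1.76. That change of scale moves all genes alike (median of all genes 0.051 in place of 0.024), so it could not decide on scaling. For the list as a whole, the values argue against a higher start in knockout cells. Treated knockout cells lay below treated parent cells by -1.398, with 32 of 38 members lower and 1 higher. A higher start is not excluded for RHOB (6.763 CPM in treated knockout and 5.174 CPM in treated parent cells), and for DUSP4 and KLF6 the untreated difference (2.83 and 1.18) had most of the size of the difference of responses (-3.52 and -1.35). A dependence of this response on SLFN11 may account for the pattern. A difference between the lines other than SLFN11 stays open and untested, because the design has 1 knockout line.

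Histone genes fell in knockout cells and had a median of 0.15 in parent cells. The reads that no other gene overlaps (median -1.37 in knockout cells) kept 100% of the histone exon reads at the median. They do not remove reads of a copy at another place, so reads shared between gene copies cannot be told apart. By intron reads, all 7 histone genes measured fell in knockout cells (median -1.49; camera adjusted p = 0.0021 with an estimated correlation). In parent cells 4 of the 7 rose and 1 fell. The difference of responses had a median of -1.79 (camera adjusted p = 0.00169 with an estimated correlation). Intron reads may be shared between copies too, so these values do not settle the sharing. A change in the capture of RNA without a poly(A) tail is argued against by 548 other small RNA genes, whose median in knockout cells was -0.054, with 8 lower and 3 higher. Most of these are low, and the 52 of at least 10 CPM had a median of -0.123. A difference in S phase progression between the genotypes could account for the pattern and was not tested, since no cell cycle measurement was used here.

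Long genes fell under camptothecin in both genotypes by exon reads. The parent difference was -0.24 without parent control replicate 1, and -0.27 with a smooth trend on the length of the mature RNA removed, so neither accounts for the whole of it. The test of GC content is void for the classes as a whole, because 52% of short genes had a GC value against 90% of long ones. Among the genes with a value the parent difference was -0.36, and -0.25 (spread 0.014 over resampled genes) with a smooth GC trend removed. In knockout cells these values were -0.23 and -0.18. For the genes covered, the parent values argue against GC content as the whole source. For the other genes it cannot be told apart. Blocked elongation is a candidate explanation that stays open, and the intron-read difference in parent cells was -0.043.

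Other splits of the same libraries were counted. For the parent response 6523 genes were called with the real split and 2 in the highest other, for the knockout response 5932 and 1, and for the untreated cells 2104 and 1. By intron reads it was 4513 and 0 in parent cells and 3962 and 1 in knockout cells. In each of these 1 of 10 splits, the real one, called as many genes, and 10 splits are too few for a share under 0.05. For the difference of responses, 6 of 100 drawn relabellings, the real one included, called as many genes (1487 with the real labels, 3968 in the highest other), and by intron reads 6 of 100 (1158 and 2104), so chance is not excluded by this count. The 5 others in each mixed the knockout labels and left the parent labels whole or exchanged, so they count the parent response itself, a structure of the samples, as a difference. The 77 draws that mixed both genotypes called at most 1 gene. Those draws, like the other splits of each comparison, put libraries that differ by treatment or genotype in the same group. That widens the spread within groups, so few calls were set in advance. The low counts are therefore no evidence for the results.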

How the results depend on the processing

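The alternative that left out parent control replicate 1 and knockout camptothecin replicate 3 together was chosen only after the result was seen. By exon reads, the number of calls of the parent response stayed within 1.5 times of 7978 under every alternative that was run, and those of the other comparisons did not. Of the results for single genes under alternatives, 5745 kept direction and side of the threshold, 263 lost the call, 7 gained it and 2 reversed, and of the lists 1092, 81, 36 and 51. The single genes followed were named genes called with all libraries and the genes always named, so few could gain a call. These counts are no rate over all genes. They leave out SLFN11 in untreated cells, and the immediate early and histone lists except in untreated cells. The direction of a list is that of its test, and values are medians of log2 changes. The cause was not tested unless stated. In simulated counts of this depth and number of libraries, 38.8% of genes changed by 1.5-fold were recovered for the difference of responses. Only 200 of the 22931 genes in that fit were changed, all with a mean of at least 1 CPM. The share is therefore not the sensitivity of the real test, which called 1487 genes.

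With library size alone, 5967 genes were called in knockout cells (4693 higher, 1274 lower), 860 had a more positive difference and 1073 were lower in untreated knockout cells. The direction turned for DNA repair genes (0.089), myeloid (0.084) and erythroid markers (0.78) in knockout cells and heat shock genes in untreated cells (0.059). By intron reads it called 4248 higher and 1866 lower genes in parent and 2656 and 1116 in knockout cells.

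Without a filter on low counts 778 genes had a more positive difference and the call of IGHV3-15 for it ended (edgeR adjusted p = 0.068), and with DESeq2 817 genes had one. With only the groups compared, 5932 genes were called in knockout cells (2762 higher) and 2104 in untreated cells (788 lower). These fits hold fewer libraries. With total gene reads 781 genes had a more positive difference, CSF1R reversed in parent cells (-0.009) and in untreated cells (-0.16), and SLFN11 lost its call (-0.12). The list direction turned for schlafen genes in parent cells (-0.21), myeloid (-0.077) and erythroid markers (0.54) in knockout cells, epithelial markers in the difference (-0.063), and NF-kappaB targets (-0.022) and myeloid markers (-0.063) in untreated cells.

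Without both parent control replicate 1 and knockout camptothecin replicate 3, 7330 genes were called in knockout cells (3396 higher, 3934 lower), 5005 in the difference (2083 and 2922) and 5918 in untreated cells (3123 and 2795). The genes called with all libraries were kept in 1472 of 1487 cases for the difference. List directions turned in knockout cells for mitochondrially encoded genes (0.029), B-lineage (0.032) and erythroid markers (0.087), in the difference for DNA replication (-0.009), DNA repair (-0.004), schlafen (0.001) and epithelial markers (-0.11), and in untreated cells for heat shock (0.082) and mitotic genes (0.034). List calls ended for ribosomal protein genes in knockout cells, mitochondrially encoded genes in the difference, and interferon-stimulated, DNA repair and schlafen genes in untreated cells, and were gained for mitotic and ribosomal protein genes in the difference and T lymphoblast genes in untreated cells. In knockout cells EGR1 lost its call (edgeR adjusted p = 0.0507) and IER2 gained one (0.0117), as did SLFN11 in parent cells (0.13, adjusted p = 0.000601). The length difference of the responses was 0.001 and lost its call. By intron reads 2877 genes were lower in knockout cells, and 1465 and 1441 differed in response.

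Of 37 list calls, 11 held with an estimated correlation, and the histone list in parent cells (0.145) lost its call with it. With fry the schlafen list in parent cells (0.03) turned, and calls ended for ribosomal protein genes in knockout cells, mitochondrially encoded genes in the difference, and histone, DNA repair and mitochondrially encoded genes in untreated cells. Fry, which does not compare a list with other genes, gained 14 list calls. In parent cells these were ATF4 and unfolded protein response genes (fry adjusted p = 5.91e-06), B-lineage markers (0.000179), the BCL2 family (0.000281), myeloid markers (0.00184), interferon-stimulated genes (0.00989), erythroid markers (0.0319) and DNA repair genes (0.0385). In knockout cells they were ATF4 and unfolded protein response genes (0.000938) and the BCL2 family (0.0174), and for the difference p53 targets (0.00406) and myeloid markers (0.0353). In untreated cells they were T lymphoblast genes (0.000858), the BCL2 family (0.00293) and myeloid markers (0.033). With library size alone the list call of ribosomal protein genes ended in knockout cells and was gained for the difference (camera adjusted p = 0.0219). By exon length the length difference of the responses was 0.034 and lost its call. By intron reads the length difference was -0.043 in parent cells, which lost its call, and it turned to 0.067 in knockout cells. With the scale of the exon counts, intron reads called 856 lower genes in knockout cells and 339 and 264 in the difference.

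Replicate numbers were shared between groups but did not pair the libraries: same-number correlations of deviations ran from -0.03 to 0.04, and 6 of 12 libraries correlated best with their own number. With the replicate number as a block, 7931, 3723, 1348 and 3530 genes were called in the parent, knockout, difference and untreated comparisons, and 36 lists, and SLFN11 was at -0.37. The schlafen list in parent cells (0.03) turned in direction with the block. Calls also ended with the block for ATF3 and RP5-998N21.10 in knockout cells (edgeR adjusted p = 0.0507 and 0.0685), for CD3G, PCNA and FLJ27365 in the difference (0.0522, 0.0593 and 0.0735) and for the B-lineage list in the difference (camera adjusted p = 0.0509). Those of CD79B in knockout cells (edgeR adjusted p = 0.0519) and of ATF3 and CSF1R in untreated cells (0.0626 and 0.0591) ended too.

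Leaving out each library in turn gave 2519 to 6640 calls in knockout cells (945 to 3157 higher, 1537 to 3483 lower), 903 to 3503 in the difference (179 to 1241 and 720 to 2262) and 2385 to 4327 in untreated cells (998 to 2279 lower). The genes called with all libraries were kept in 1475 of 1487 cases for the difference without parent control replicate 1. List medians ran in parent cells from -0.097 to 0.105 for schlafen genes and 0.089 to 0.26 for epithelial markers. In knockout cells they ran from 0.03 to 0.201 for mitochondrially encoded genes, -0.223 to 0.305 for B-lineage, -0.34 to 0.39 for myeloid and -0.026 to 0.58 for erythroid markers. In the difference they ran from -0.019 to 0.12 for DNA replication genes and -0.078 to 0.072 for epithelial markers. In untreated cells they ran from -0.13 to 0.081 for heat shock genes, -0.17 to 0.033 for mitotic genes and -0.15 to 0.42 for B-lineage markers. By intron reads 955 to 2233 genes were higher in knockout cells, and 330 to 1047 and 353 to 1010 differed in response.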

Other observations

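The tests of MAP kinase phosphatases and of SLFN11 intron reads were chosen only after the result was seen. Intron reads of single gene groups, not described so far, gave NF-kappaB targets higher in 10 of 15 cases in parent cells (median 1.55; camera adjusted p = 0.0117 with an estimated correlation), with 9 of 15 more negative in knockout cells (median -0.86; adjusted p = 0.00562 with an estimated correlation). All 8 heat shock genes with measured introns fell, with medians of -1.42 in parent cells (adjusted p = 0.0174 with an estimated correlation) and -0.99 in knockout cells (adjusted p = 0.0158 with an estimated correlation), and a difference of 0.42 (camera adjusted p = 0.00149; adjusted p = 0.188 with an estimated correlation). T lymphoblast genes fell in 18 of 26 cases in parent and 16 in knockout cells (medians -0.41 and -0.33; adjusted p = 0.00195 and 0.00125 with an estimated correlation), and differed by 0.13 (camera adjusted p = 0.0351; adjusted p = 0.0969 with an estimated correlation). DNA replication genes rose in 21 of 39 cases in knockout cells (median 0.24; adjusted p = 0.00599 with an estimated correlation), and 14 rose and 2 fell in parent cells (median 0.17; camera adjusted p = 0.00113; adjusted p = 0.0777 with an estimated correlation). By intron reads that list was called for the difference too, unlike by exon reads (median 0.16, 2 of 39 more positive and 1 more negative; camera adjusted p = 0.00926; adjusted p = 0.168 with an estimated correlation).

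A hypothesis was that MAP kinase phosphatases outside the immediate early list respond like DUSP8. Without DUSP8, which prompted it, 4 of DUSP6, DUSP7, DUSP9, DUSP10 and DUSP16 were measured, and the group had a more negative response in knockout cells (camera p = 0.00329; p = 0.0175 with an estimated correlation; median -0.70). DUSP10 (-2.61) and DUSP16 (-1.42) carried this, while DUSP6 (0.03) and DUSP7 (0.18) did not pass the test. In parent cells DUSP10 and DUSP16 rose and DUSP6 fell, so the group did not rise as a whole like DUSP8.

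SLFN11 had fewer exon and more intron reads in untreated knockout than in parent cells, with an intron minus exon difference of 0.95. A higher share of intron reads in the knockout libraries as a whole is argued against, because 0.09% of 9779 genes differed as much and their median was 0.02. Less mature RNA per unspliced SLFN11 RNA in the knockout is a hypothesis that stays open and untested. A copy number difference between the lines could shift whole stretches of chromosomes. In the untreated comparison, 0 of 254 windows of 10 Mb had an absolute median above 0.3 (largest 0.28). This argues against gains or losses that shift the median of such a window by more than 0.3. Shorter ones and smaller shifts stay open.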
